A study of Danio rerio with 6 samples.

How the data were processed

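tRNA was sequenced from wild-type TU zebrafish eggs and embryos at 6 stages with 1 library per stage. Per the labels' protocols, total RNA came from about 50 to 100 eggs or embryos, and RNA of 60 to 120 nt was taken from a gel (the sample descriptions give 60 to 100 nt). It was deacylated, its ends were repaired, and a mixture of ALKB enzymes removed some of the base modifications that block reverse transcription. Reads shorter than this size class, such as 5' fragments, were not analysed here. Per the submitters' processing notes the tools were cutadapt 3.4 and Bowtie2 2.4.2 and the genome build was GRCz11. The roles of the tools, their settings, the rule that put a read in a table and the treatment of reads shared by several tRNA genes are not given in the sources used here.

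The authors deposited both tables in RPM, reads scaled to the size of the library, as the authors named the tables. The first lists distinct cytoplasmic read sequences with an amino acid and an anticodon, the second the 22 mitochondrial tRNAs. All 3021 sequences were 60 to 95 nt long, 66.7% of them ended in CCA, and none occurred 2 times. The comparisons had been planned for tables of tRNA genes, so the read sequence took the place of the gene and the sum over an anticodon label was the main unit. Gene positions, gene copy numbers and pseudogene marks were not used here. In each library every deposited RPM value was a whole multiple of a single step, the value of 1 read, which gave the library total and the read counts. The step made 100% of the values whole within 0.01 reads, and the same total held for both tables. The library totals were 7096801 reads in egg, 6094181 at 1cell, 3324546 at 256cell, 5892692 at sphere, 4211882 at shield and 6148047 at 24hpf. Between 16.8% and 34.2% of the reads of a library were in neither table.

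RPM values were summed per anticodon label, a pseudocount of 1 RPM was added, and the sum was divided by the library's cytoplasmic total, so that every log2 ratio is on the log2(value + pseudocount) scale and understates the difference of rare tRNAs. Anticodons with a mean of at least 10 RPM over the 6 libraries were compared, which kept 35 of 38 and left out Thr-AGT, Tyr-GTA and Ala-TGC. Differences of at least 1 on the log2 scale (2-fold) were counted. With 1 library per stage these counts rest on size alone, and an edgeR test added later was the only test across libraries. Intervals for shares are exact Clopper-Pearson intervals on the read counts, intervals for ratios come from the exact binomial interval for the reads of 2 libraries, and both are at the 95% level. The floor of each library is 3 reads, or 0.423, 0.492, 0.902, 0.509, 0.712 and 0.488 RPM from egg to 24hpf. Stages were taken in 3 comparisons: 24hpf against egg, the mean of the 3 later against the mean of the 3 earlier stages, and each stage against the one before. Mitochondrial tRNAs were compared as shares of the mitochondrial total and as RPM.

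Lists of tRNAs were the 5' fragment donors (Gly-GCC, Gly-CCC, Glu-CTC, Glu-TTC, Lys-CTT, Val-CAC, Val-AAC, His-GTG, Asp-GTC), groups by the chemistry of the amino acid, type II tRNAs, groups by the first anticodon base, and heavy- and light-strand mitochondrial tRNAs. The median of a list was placed among 10000 random lists of the same size, drawn within 5 bins of mean abundance. The members of the list itself could be drawn, so a list that fills much of a bin is set largely against itself. trnS1 and trnS2 stayed out of the strand lists because their names do not give the anticodon. Named items followed a rule of size: the 10 most abundant anticodons, up to 12 highest and 12 lowest past the 2-fold size in each main comparison or the 5 most extreme where fewer passed, all 5' fragment donors and initiator methionine. Selenocysteine tRNA was on that list too and had no sequence under its label in the table. For mitochondrial tRNAs the rule took the 5 most abundant, 4 highest and 4 lowest, and for single sequences the 5 most abundant, 5 highest and 5 lowest with a mean of at least 100 RPM. The design, the lists, the naming rule and the main settings were chosen before the data were examined, and the later additions are named where they are used.

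The anticodon labels are the authors'. Most listed sequences held the bases of the labelled anticodon somewhere, but only 0 of 4 Leu-AAG, 0 of 1 Leu-TAG, 1 of 9 Ser-AGA, 0 of 2 Ser-TGA, 0 of 2 Thr-CGT and 11 of 20 Val-TAC sequences did. A match at any place counted, so it does not show that these bases lie in the anticodon loop. In the main read of Arg-ACG, for example, ACG occurs only near the 5' end, ahead of that loop. Anticodons were kept as labelled.

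Families were formed after the single sequences had been seen, by joining sequences of an anticodon that overlapped exactly over at least 50 nt. The family with the highest mean RPM led, and other families were aligned to it without gaps and kept with up to 5 substitutions. This gave 687 families, of which 474 had a mean of at least 10 RPM.

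As an alternative added after whole reads had been recovered, edgeR's quasi-likelihood test was run on the read counts of the 35 anticodons, with the stages of each side taken as if replicates. Libraries were scaled there by edgeR's trimmed-mean factors, not by share. The test called 1 anticodon higher (Lys-TTT, log2 fold change 2.88, adjusted p 0.00784 by Benjamini-Hochberg) and 0 lower in the later stages, and 7 had an unadjusted p under 0.05. Other alternatives changed the scaling, the pseudocount, the filter, the stage left out, the reference library and the read end.

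The recovery of totals, the 24hpf against egg ratios, the list percentiles, the substitution counts and the edgeR test were tested on simulated data. The other comparisons were not simulated. The totals of 6 of 6 simulated libraries were recovered. For 24hpf against egg with 35 anticodons, 5 of 5 that were changed 4-fold were called, 0 of 5 changed 1.5-fold and 0 of 25 unchanged were called, and 94.3% of the intervals held the true ratio. Beyond the set changes these simulated libraries differed by counting error alone. The result therefore gives no error rate for real libraries, which can differ in other ways. A list of 7 members raised by 1 on the log2 scale reached percentile 98.1, random lists had a median percentile of 51.3, and 100 of 100 known substitution counts were recovered. The edgeR test called 10 of 10 anticodons changed 4-fold and 0 unchanged ones. Its simulated libraries were drawn with a fixed spread that was not taken from the data. The calls therefore do not show its power or error rate for the real stages. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures used matplotlib 3.10.9, and the count test used R 4.3.3 with edgeR 4.0.16.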

Results

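RNA of tRNA size was sequenced from wild-type TU zebrafish at 6 points of early life, with 1 library each: mature egg, 1cell, 256cell, sphere, shield and 24hpf (24 hours after fertilisation). The first 3 stages precede broad transcription from the embryo's own genome, and the last 3 follow its start. RNA was gel-selected by size, so the libraries were aimed at long tRNA molecules and not at the short fragments made from them. Whether the molecules behind the listed reads were complete was not tested. Each library held 3324546 to 7096801 reads, of which 1877927 to 4770871 fell in the table of cytoplasmic tRNA reads and 241206 to 1432257 in the table of mitochondrial tRNAs. The cytoplasmic table listed 3021 different read sequences of 60 to 95 nt under 38 pairs of amino acid and anticodon, covering 18 amino acids. Because no stage was sampled more than 1 time, no difference between stages has a replicate check, and every interval given is a 95% interval for counting error only. PCR reads without molecular identifiers are not independent molecules, so these intervals are narrower than the true error.

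The first question was which tRNAs make up the listed reads at each stage. His-GTG, the tRNA that decodes histidine codons, dominated the listed cytoplasmic reads in all 6 libraries. It held 89.1% of them in egg (exact Clopper-Pearson interval 89.1 to 89.2), 81.7% at 1cell, 87.1% at 256cell, 84.4% at sphere, 84.7% at shield and 89.0% at 24hpf. The next most abundant tRNAs were Asp-GTC with a mean of 3.54% over the 6 libraries, Lys-CTT with 2.85%, Glu-TTC with 2.44%, Gly-GCC with 1.52% and Gln-CTG with 1.29%. Arg-ACG followed with 0.622%, Asn-GTT with 0.329%, Gly-CCC with 0.248% and Gln-TTG with 0.209%. Together the 7 most abundant anticodons held at least 97.3% of the listed cytoplasmic reads in every library. Among reads other than His-GTG, Asp-GTC, Glu-TTC, Lys-CTT, Gly-GCC and Gln-CTG together held 84.8% in egg and 85.1% at 24hpf, with a low of 79.3% at 1cell. Reads ending in CCA, the tail added to mature tRNAs, made up 86.1% to 90.4% of the listed cytoplasmic reads. Over all libraries they were 94.3% of the His-GTG reads, 88.0% of Gly-GCC, 82.5% of Gln-CTG and 59.5% of Glu-TTC. The part was lower in Arg-ACG (46.9%), Asp-GTC (22.6%) and Lys-CTT (13.4%). Reads of 60 to 67 nt, shorter than a complete tRNA, made up 96.9% to 98.7%, and among the reads of at least 70 nt His-GTG held only 3.21% to 6.65%. The His-GTG share, like that of every other anticodon here, is therefore a share of the reads listed, not of tRNA molecules in the embryo. Ratios between stages compare such shares. As a percentage of the whole library His-GTG ranged from 34.6 at 1cell to 69.1 at 24hpf.

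**Figure D1:**
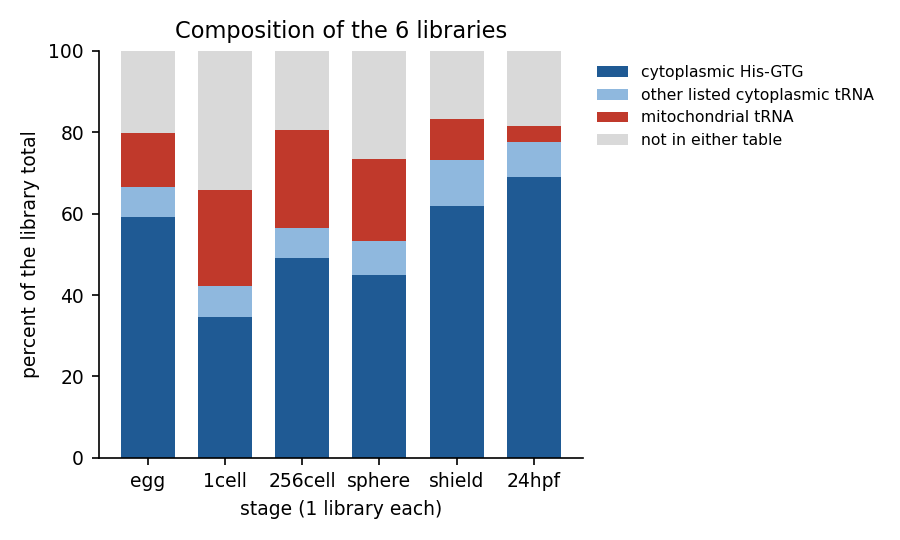
Stacked bars give the percent of each library total (1 library per stage, y axis in percent) in cytoplasmic His-GTG, other listed cytoplasmic tRNAs, mitochondrial tRNAs and reads in neither table. The mitochondrial part was 24.2% at 256cell and 3.92% at 24hpf, while His-GTG held 49.2% and 69.1%.

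Mitochondrial tRNAs, which serve protein synthesis inside mitochondria, took a large part of the early libraries and a small part of the 24hpf library. Of the reads listed in either table they held 16.8% in egg (exact interval 16.8 to 16.9), 35.7% at 1cell, 30.0% at 256cell, 27.4% at sphere, 12.04% at shield and 4.81% at 24hpf (4.79 to 4.83). Against the whole library the shares were 13.4%, 23.5%, 24.2%, 20.1%, 10.0% and 3.92%, in the same order. The mitochondrial RPM was 6.16 times as high at 256cell as at 24hpf and 3.43 times as high in egg as at 24hpf. Between egg and 1cell, which both precede broad embryonic transcription, it already differed 1.75-fold.

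The comparison of 24hpf with egg spans the whole series and asks how the listed cytoplasmic reads at the end of the first day differ from those in the egg. Valine tRNA Val-TAC stood out on the higher side, with 314 RPM in egg and 3653 RPM at 24hpf, 9.93 times its share in egg (log2 3.31, counting interval 3.25 to 3.38). That label joins 2 kinds of sequence, split after the values were seen: those with TTTACAC, which holds the anticodon, went from 162 to 3583 RPM (log2 4.24), and the others from 152 to 69.8 RPM (-1.34). Arginine tRNAs were higher too, with Arg-CCT at 1.58 (1.38 to 1.86), Arg-TCT at 1.55 (1.43 to 1.70) and Arg-ACG at 1.17 (1.14 to 1.21) on the log2 scale. Glu-CTC was higher by 1.35 (1.28 to 1.43), and the rare Lys-TTT and Trp-CCA by 1.49 (1.16 to 2.10) and 1.15 (0.82 to 1.65). These 7 were the only anticodons at least 2-fold higher among the 35 with a mean of at least 10 RPM, and 15 were at least 2-fold lower. The larger acidic and basic families moved less, with Glu-TTC at 0.69, Asp-GTC at 0.48 and Lys-CTT at 0.40, and His-GTG, which makes up most of the total it is divided by, was at 0.00. With RPM, median-ratio and trimmed-mean scaling His-GTG was at 0.22, 0.68 and 0.75. With 256cell in the place of egg, an alternative added after the data were seen, Arg-TCT turned to -0.17 and Arg-CCT to -0.12. In that setting Arg-ACG was at 0.11, Lys-TTT at 0.68, Asp-GTC at -0.02 and Lys-CTT at -0.05. Over the alternatives run, Val-TAC stayed between 3.06 and 4.07 and Glu-CTC between 1.30 and 2.11. Trp-CCA ended below 2-fold at 0.68 with a pseudocount of 10 RPM, as did Lys-TTT at 0.84, and with only sequences ending in CCA Arg-ACG was at 0.94 and Asp-GTC turned to -0.66.

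Glycine, glutamine and proline tRNAs made up much of the lower side. Gly-CCC was lowest at -2.86 (-2.94 to -2.79), with 1708 RPM in egg and 274 RPM at 24hpf, and the abundant Gly-GCC was at -1.44 (-1.46 to -1.43). Gln-TTG was at -2.24 (-2.31 to -2.19) and Gln-CTG at -1.19 (-1.20 to -1.17), and Asn-GTT, which carries the other amide amino acid, was at -1.72 (-1.79 to -1.66). The 4 proline tRNAs were all at least 2-fold lower, with Pro-AGG at -2.51, Pro-CGG at -2.03, Pro-GGG at -1.30 and Pro-TGG at -1.19. The initiator methionine tRNA iMet-CAT, which starts translation, was at -1.98 (-2.15 to -1.85), and Met-CAT, which reads internal methionine codons, at -1.75 (-2.87 to -1.28). The remaining 4 were rare: Thr-TGT at -2.59 (-3.95 to -2.22), Val-CAC at -2.15 (-2.73 to -1.84), Thr-CGT at -2.14 (-2.65 to -1.84) and Leu-CAA at -1.36. Gly-CCC, Gln-TTG, Pro-AGG, Pro-CGG, Thr-TGT, Thr-CGT and Val-CAC stayed at least 2-fold lower in every alternative that kept them. Gly-GCC was at -0.76 with median-ratio scaling and -0.69 with trimmed-mean scaling, where Gln-CTG was at -0.50 and -0.43 and Pro-TGG at -0.51 and -0.44. In the same 2 scalings Pro-GGG was at -0.62 and -0.55 and Leu-CAA at -0.68 and -0.61, and in RPM Gln-CTG was at -0.96 and Pro-TGG at -0.97. Trimmed-mean scaling also left Asn-GTT at -0.97, and with 256cell in the place of egg iMet-CAT was at -0.97, while a pseudocount of 10 RPM left Met-CAT at -0.87.

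How many tRNAs counted as higher or lower depended on the scaling between libraries. The median log2 ratio over the 35 anticodons was -0.66, and scaling by RPM shifted it by 0.22, median-ratio scaling by 0.69 and trimmed-mean scaling by 0.76. In the main scaling 7 were higher and 15 lower, with median-ratio scaling 10 and 10, and with trimmed-mean scaling 10 and 8. The higher ones were thus 31.8%, 50% and 55.6% of the 2-fold differences. The counting interval excluded 0 for 33 of the 35. A wider yardstick came from the egg, 1cell and 256cell libraries, whose pairwise differences had a median size of 0.55 and a 95th percentile of 1.95 on the log2 scale. Only Val-TAC was higher by more than that percentile, and 8 anticodons were lower by more.

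**Figure D2:**
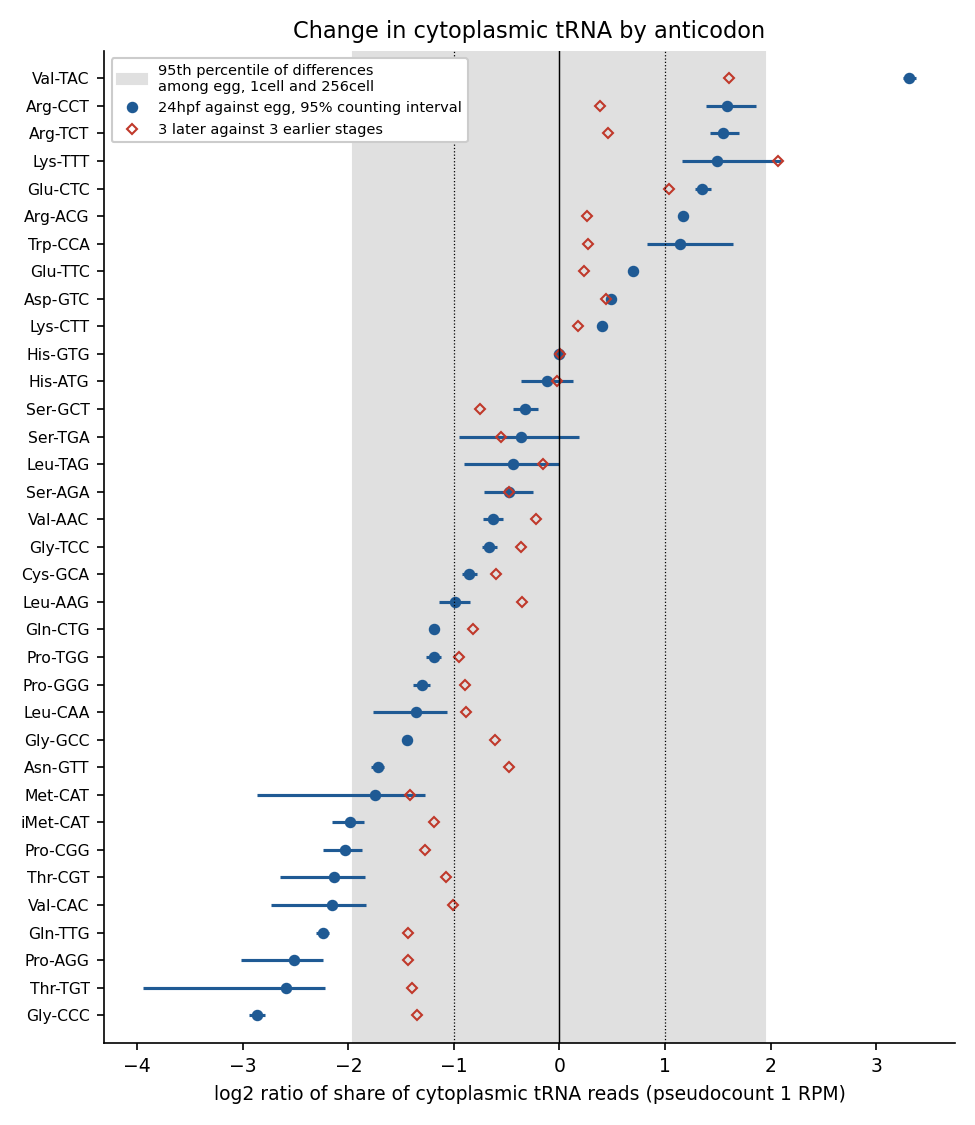
Filled points give the log2 ratio of each anticodon's share of cytoplasmic tRNA reads at 24hpf over egg (x axis, pseudocount 1 RPM) with 95% counting intervals, open diamonds give the 3 later over the 3 earlier stages, and the grey band marks the 95th percentile of differences among egg, 1cell and 256cell. Val-TAC at 3.31 lies right of the band, and Gly-CCC at -2.86 is the lowest of the 35 anticodons on the y axis.

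The study concerns 5' fragments, front parts of tRNAs cut near the anticodon, and the tRNAs whose 5' fragments are commonly reported in vertebrates did not move together here. Of these 9 donors Glu-CTC was at least 2-fold higher at 24hpf than in egg, Gly-CCC, Val-CAC and Gly-GCC were at least 2-fold lower, and 5 lay between, with Val-AAC at -0.63. Their median was -0.00, at the 67.8th percentile of 10000 random lists of the same size matched on mean abundance. That median is the value of His-GTG, which share scaling holds near 0. The donors also fill most of the most abundant bin, so the percentile does not show whether they differ from other tRNAs. With median-ratio or trimmed-mean scaling 4 of the 9 were at least 2-fold higher, and the list median was 0.68 and 0.75.

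Tests of the other lists set their medians against the same kind of random lists, as a description of these 2 libraries. The basic tRNAs (Arg, Lys, His) had 4 of 7 members at least 2-fold higher and none lower, with a median of 1.17 at the 99.1th percentile. With 256cell in the place of egg that median turned to -0.05, and it was 0.32 with only sequences ending in CCA. The summed share of the list, mostly His-GTG, was at 0.01. Acidic tRNAs (Asp, Glu) had 1 of 3 higher and a median of 0.69, at the 86.7th percentile. All 4 proline tRNAs were lower, with a median of -1.67 at the 8.86th percentile. All 3 amide tRNAs (Asn, Gln) were lower, with a median of -1.72 at the 9.45th percentile. Sulphur-containing amino acids (Cys, Met) had 2 of 3 members lower and a median of -1.75 at the 27.9th percentile, with Cys-GCA at -0.85. Glycine tRNAs, the part of the small amino acids past the filter, had 2 of 3 lower and a median of -1.44 at the 17.9th percentile. Trp-CCA was the only aromatic member past the filter. The filter left out Ala-TGC of the small list, at -1.95 (-6.73 to -1.59) with 24 reads in egg and 2 at 24hpf. It also left out the aromatic Tyr-GTA, at -1.96 (-4.98 to -1.52) with 32 and 4 reads, opposite to Trp-CCA, and both are named after their values were seen.

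Branched amino acids (Val, Leu) had 1 of 6 higher and 2 lower, and their median of -0.81 (58.5th percentile) went against their summed share at 1.96, which Val-TAC carries, and turned to 1.34 with a filter of 100 RPM. Hydroxyl amino acids (Ser, Thr) had 2 of 5 lower and a median of -0.48 (61.3th percentile), which turned to 0.21 and 0.28 with median-ratio and trimmed-mean scaling. The type II tRNAs with a long variable arm (Leu, Ser) had 1 of 6 lower and a median of -0.46 (68.2th percentile), which turned to 0.23 and 0.30. By the first anticodon base, tRNAs starting with C had 3 of 12 higher and 8 lower, with a median of -1.56 at the 3.93th percentile. That median was -0.87 and -0.80 with median-ratio and trimmed-mean scaling, and the summed share was at -0.21. tRNAs starting with T had 3 of 10 higher and 3 lower, with a median of -0.40 at the 96.5th percentile that turned to 0.29 and 0.36 under the same scalings. Those starting with A had 1 of 6 higher and 1 lower, with a median of -0.55 (43.1th percentile) that turned to 0.13 and 0.20. Those starting with G had 3 of 7 lower and a median of -0.85 (32.9th percentile).

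The 3 stages after the start of broad embryonic transcription were then compared with the 3 before it. By share, Val-TAC (log2 1.61) and Glu-CTC (1.04) were higher in each later library than in every earlier one, while Gln-TTG (-1.44) and Gln-CTG (-0.82) were lower in each. These 2 above and 2 below, out of 35, are about the 10% of cases that chance alone separates. Which tRNAs separated in this way depended on the scaling, with 8 above and 4 below in RPM, 6 and 6 with median-ratio scaling and 3 and 9 in the share without His-GTG. Val-TAC and Gln-TTG separated in all 4 scalings, while Glu-CTC did not with median-ratio scaling or without His-GTG, and Gln-CTG did not with median-ratio scaling. Asp-GTC and Lys-TTT lay above in the 3 scalings other than the main share, and Pro-CGG and Pro-TGG below. The Gln-CTG difference was -0.32 with median-ratio scaling and -0.08 in the edgeR test. Lys-TTT, measured through a single read sequence, had the highest mean difference at 2.07, with 87.4 RPM at sphere, 107 RPM at shield and 26.3 RPM at 24hpf against 7.33, 16.9 and 11.4 RPM in egg, 1cell and 256cell. Its share at 24hpf (0.00340%) lay below that at 1cell (0.00399%), and its single sequence does not end in CCA. Val-TAC, Glu-CTC and Lys-TTT were the only 3 anticodons at least 2-fold higher, and the next were Arg-TCT at 0.46 and Asp-GTC at 0.44. At least 2-fold lower were 9: Gln-TTG, Pro-AGG at -1.44, Met-CAT at -1.42, Thr-TGT at -1.40, Gly-CCC at -1.35, Pro-CGG at -1.28, iMet-CAT at -1.19, Thr-CGT at -1.08 and Val-CAC at -1.01. Chance separates 3 libraries from 3 others in 10% of cases, and the smallest exact permutation p of this design is 0.1, so no exact permutation test of them can reach 0.05. The edgeR quasi-likelihood test on the reads, added after the data were seen and taking different stages as if replicates, called Lys-TTT alone (log2 fold change 2.88, adjusted p 0.00784). Its log2 fold changes for Val-TAC and Glu-CTC were larger than the size comparison gave, at 3.48 (adjusted p 0.195) and 2.10 (adjusted p 0.204), and 10 anticodons had a log2 fold change of at least 1. edgeR scaled the libraries by its own trimmed-mean factors, so its folds are not on the scale of the shares. His-GTG, for example, was at 0.87 in edgeR and 0.00 by share, and Gly-GCC at 0.03 and -0.61.

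A large part of this comparison came from the 24hpf library. Without it the number at least 2-fold higher went from 3 to 1 and the number lower from 9 to 1, with Val-TAC at 0.83, Glu-CTC at 0.83, Gly-CCC at -0.45 and Gln-TTG at -0.99. The number lower was 5 without 1cell and 15 without sphere, and Glu-CTC was at 0.90 without 1cell and 0.96 without shield. The median over the 35 anticodons was -0.48, and RPM scaling shifted it by 0.31 and median-ratio scaling by 0.50. Of the 2-fold differences 25% were higher in the main scaling, 37.5% in RPM and 100% with median-ratio scaling, where none was lower.

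Among the lists, the 5' fragment donors had 1 of 9 higher (Glu-CTC) and 2 lower (Gly-CCC and Val-CAC), with a median of 0.00 at the 67.8th percentile. That median was again the value of His-GTG, and the same limit holds for the percentile. The acidic and basic tRNAs had medians of 0.44 (95.8th percentile) and 0.26 (95.9th), and the basic median was -0.11 without egg. Proline tRNAs had 2 of 4 lower with a median of -1.12 at the 4.98th percentile. Medians of the amide, sulphur, small and hydroxyl lists were -0.82 (18.0th), -1.19 (17.4th), -0.61 (27.0th) and -0.75 (49.0th), and the type II median was -0.52 (52.1th). The branched median of -0.29 (82.3th) turned to 0.02 in RPM. First base C gave -0.95 (2.88th), T gave -0.26 (96.5th), A gave -0.29 (43.9th) and G gave -0.60 (32.5th), and T and A turned to 0.05 and 0.02 in RPM.

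Steps between neighbouring stages showed where the composition moved. From shield to 24hpf Val-TAC was higher by 2.06 and Trp-CCA was also at least 2-fold higher, while 12 anticodons were lower, led by Asn-GTT at -2.64 (6 lower with median-ratio scaling and 7 without His-GTG). From 256cell to sphere only Lys-TTT, at 2.91, and Asn-GTT were at least 2-fold higher and none was lower. Glu-CTC had the highest ratio from sphere to shield at 0.75, where 8 anticodons were lower, led by Ser-AGA at -1.24. Asn-GTT went up and down, with 0.174% of the cytoplasmic reads in egg, 0.736% at 1cell, 0.184% at 256cell, 0.500% at sphere, 0.328% at shield and 0.0526% at 24hpf. Egg and 1cell, on either side of fertilisation, differed for 15 anticodons in the share scaling, all higher at 1cell and led by Arg-CCT at 2.63, and 1cell and 256cell for 4, all lower at 256cell. The number of lower anticodons from sphere to shield was 0 in RPM and with median-ratio scaling, and from egg to 1cell RPM gave 6 higher and 2 lower, median-ratio scaling 5 higher and 6 lower, and the share without His-GTG 5 higher and 4 lower. Across anticodons, which are not independent replicates, Pearson's r of log2 shares ranged from 0.97 to 0.99 over the 5 steps.

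**Figure D3:**
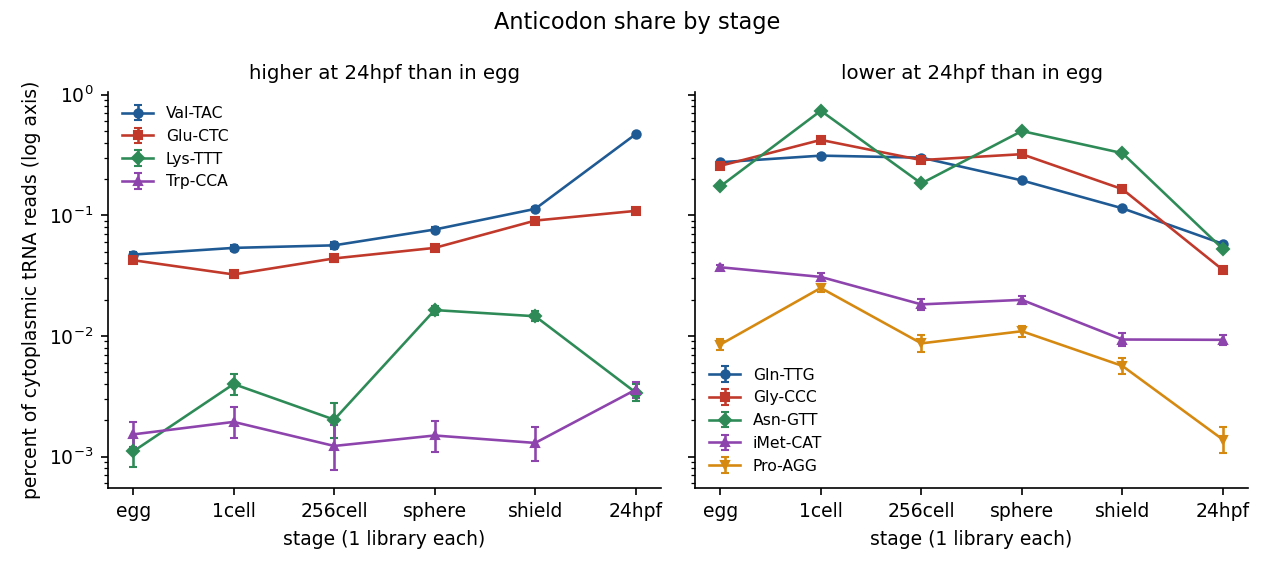
Lines join the percent of cytoplasmic tRNA reads (y axis, log scale) of named anticodons over the 6 stages (x axis, 1 library each), with 95% exact intervals for counting error, for 4 anticodons higher (left) and 5 lower (right) at 24hpf than in egg. Val-TAC goes from 0.113% at shield to 0.471% at 24hpf, and Gln-TTG from 0.301% at 256cell to 0.0580% at 24hpf, both in the share scaling.

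Within the mitochondrial pool, trnV (valine) and trnL2 (leucine) held 68.2% to 75.3% of the reads in every library. From egg to 24hpf trnV went from 31.5% to 47.3% of mitochondrial reads (log2 0.59) and trnL2 from 40.3% to 28.0% (-0.53). The egg library stood apart for both, since at 1cell trnV was already at 51.3% (0.70 against egg) and trnL2 at 17.8% (-1.18), and later against earlier stages they were at 0.08 and 0.03. The next in abundance were trnR at 9.01% and 3.62% (-1.32), trnH at 6.84% and 8.99% (0.39) and trnN at 4.40% and 3.84% (-0.19). By share, trnG (-1.71) and trnR were the only members at least 2-fold lower and none was 2-fold higher, with trnA at -0.98 and trnP at -0.95 the next lowest. At 1cell against egg trnG and trnR were at -0.18 and 0.07, while trnA and trnP were already at -1.03 and -1.16. Highest were trnS2 at 0.76, trnE at 0.69, trnT at 0.63 and trnI at 0.61. Of these, trnT and trnI were already at 0.60 and 0.68 at 1cell against egg, with trnE at 0.31 and trnS2 at -1.41. By RPM all 22 were at least 2-fold lower at 24hpf than in egg, with trnG at -3.49, trnR at -3.09, trnL2 at -2.30 and trnV at -1.19, so the direction of those with a higher share, trnV and trnS2 among them, turns with the scaling. Later against earlier stages, no mitochondrial tRNA differed 2-fold by share and 15 were lower by RPM. The 13 heavy-strand tRNAs had a median share ratio of 0.22 and the 7 light-strand tRNAs -0.19 for 24hpf over egg (-1.56 and -1.97 in RPM), and later over earlier the medians were 0.05 and -0.10. The light-strand part was 6.83% in egg and 5.52% at 24hpf, a gap no larger than that between egg and 1cell (8.23%).

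Single read sequences did not all follow the sum of their anticodon. The 5 most abundant were all His-GTG reads ending in CCA, of 62, 63, 65, 64 and 60 nt, differing in where they start, and the top 4 held 52.3% of the cytoplasmic reads in egg and 61.9% at 24hpf. First was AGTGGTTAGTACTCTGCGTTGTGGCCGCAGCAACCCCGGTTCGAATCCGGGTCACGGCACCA, with a mean of 124112 RPM and a log2 ratio of 0.09 for 24hpf over egg, and the others were at 0.17, 0.47, 0.73 and -0.26. Among the 357 sequences with a mean of at least 100 RPM, 54 were at least 2-fold higher at 24hpf and 125 were lower. The higher ones included 21 of Glu-TTC and 15 of Asp-GTC, and 91 of the lower ones were of His-GTG, all 3 anticodons below 2-fold as sums. His-GTG supplied 1293 of the 3021 listed sequences, Glu-TTC 287 and Asp-GTC 221. Their numbers among the 357 are not given here, so these counts do not mark out any of them. Highest were 3 Val-TAC reads at 5.34, 5.06 and 4.84, a Gly-GCC read at 3.09 (its anticodon was at -1.44) and an Arg-ACG read at 2.95. The Arg-ACG read held 0.00543% of the cytoplasmic reads in egg, 0.0567% at 1cell and 0.0429% at 24hpf, so its difference was already there at 1cell. Lowest were Gln-TTG reads at -4.46 and -4.04 and Gln-CTG reads at -4.31, -4.16 and -3.81. With a mean of at least 10 RPM, 240 of 1913 sequences were higher and 809 lower. At 1 RPM or more, 2858 of the sequences were detected in egg, 2955 at 1cell, 2888 at 256cell, 2926 at sphere, 2875 at shield and 2692 at 24hpf. A count of 0 allows up to 3 reads, or 0.423 to 0.902 RPM depending on the library.

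Reads of the same anticodon were joined into families where they overlapped exactly over at least 50 nt, a step chosen after the single sequences were seen. In Gly-GCC the leading family went from 9433 RPM in egg to 1527 RPM at 24hpf, while a family with 2 substitutions (A38G and C46T, counted from 1 at the 5' end of the leading family's main read) went from 296 to 2794 RPM. The main reads were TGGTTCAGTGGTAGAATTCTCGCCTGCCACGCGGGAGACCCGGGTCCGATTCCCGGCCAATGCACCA for the first and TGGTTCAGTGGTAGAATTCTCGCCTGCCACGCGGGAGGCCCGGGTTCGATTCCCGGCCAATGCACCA for the second, and relative to the first the second was higher by 5.86 (5.80 to 5.93). Gln-TTG showed the same exchange on a smaller scale, from 1572 to 108 RPM in the leading family from 104 to 155 RPM in a family with T33C and A57G and from 10.6 to 175 RPM in one with T33C and G55A. Gln-CTG went the other way, with its leading family at 4865 RPM in egg and 4858 RPM at 24hpf and a family with A58G at 3278 and 292 RPM, or -3.48 (-3.56 to -3.42) relative to it. The leading family's part of its anticodon went from 68.5% to 25.8% in Gly-GCC, from 86.0% to 23.9% in Gln-TTG and from 44.1% to 85.7% in Gln-CTG. These relative values compare reads within 1 library and do not move with the scaling between libraries.

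**Figure D4:**
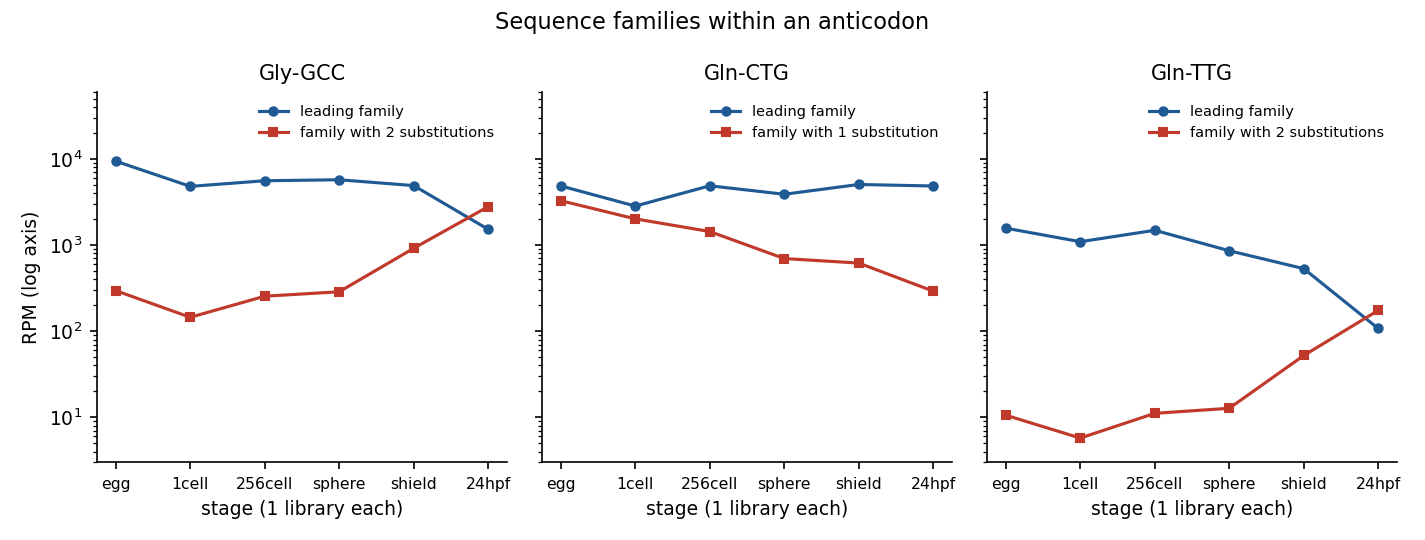
Lines give the RPM (y axis, log scale) of the leading family and of another sequence family over the 6 stages (x axis, 1 library each) for Gly-GCC, Gln-CTG and Gln-TTG, chosen after the values were seen. In Gly-GCC and Gln-TTG the lines cross between shield and 24hpf, while in Gln-CTG the family with 1 substitution goes from 3278 to 292 RPM.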

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

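The share without His-GTG, 256cell in the place of egg, CCA-ending sequences only and the edgeR test and folds were chosen after the data were seen; the other settings were planned. Of 229 alternative values for the anticodons past 2-fold between 24hpf and egg, 227 kept their sign and 206 were still at least 2-fold. For later against earlier stages 159 of 159 kept their sign and 123 were still at least 2-fold. All totals of single anticodons here include the filter settings, which leave the value of every anticodon they keep unchanged. They also include the share without His-GTG, which moves all 24hpf against egg ratios by only -0.02. Such settings could hardly change a sign or a size, so the totals overstate how firm the values are. Over single anticodons and lists, 998 of 1217 alternative values stayed within the counting interval (anticodons, 24hpf against egg) or within 0.55, the median difference among the earlier libraries (all others). Beyond it were 216, and 3 past 2-fold turned sign. Of 218 alternatives for counts and shares, 140 stayed within 1.5 times or the interval. Filters change how many items are tested, and leaving out a stage changes how many libraries enter; apart from these the cause was not tested. Depth limited the rare tRNAs most, since Thr-TGT had 14 reads and Met-CAT 18 at 24hpf. No paired analysis was possible because each stage has 1 library and the shared number 1 pairs nothing. The share of tRNA genes on chromosome 4, the relation to gene copy number, and the settings on pseudogene marks and on duplicate entries were not run, since they need gene entries that were not used here, and no sequence was listed 2 times.

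For 24hpf against egg, the number at least 2-fold higher (7) was 4 with a filter of 100 RPM, 4 with CCA-ending sequences and 3 with 256cell in the place of egg. The number lower (15) was 9 with the filter of 100 RPM and 8 with trimmed-mean scaling. With 256cell in the place of egg Arg-TCT turned to -0.17, Arg-CCT to -0.12 and the median of the basic list to -0.055. 5' fragment donors higher (1) were 4 with median-ratio and 4 with trimmed-mean scaling.

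For later against earlier stages, the number higher (3) was 10 by the size of edgeR's fold, while the edgeR test, which counts adjusted p under 0.05 and not size, called 1. It ranged from 1 to 3 when 1 stage was left out. The number lower (9) was 5 in RPM, 0 with median-ratio scaling, 5 with a pseudocount of 10 RPM, 4 with a filter of 100 RPM and 0 both by edgeR's fold and by its test. The anticodons with all 3 later libraries above all 3 earlier ones (2) were 8 in RPM and 6 with median-ratio scaling, and those below (2) were 4 in RPM, 6 with median-ratio scaling and 9 without His-GTG. The number lower ranged from 1 (without 24hpf) to 15 (without sphere) when 1 stage was left out. 5' fragment donors higher (1) ranged from 0 to 1, with 0 without 1cell, shield or 24hpf. 5' fragment donors lower (2) were 1 in RPM, 0 with median-ratio scaling, 1 with a pseudocount of 10 RPM, 1 with a filter of 100 RPM and 1 with CCA-ending sequences, and ranged from 0 to 2 with 1 stage left out.

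From egg to 1cell the number higher (15) was 6 in RPM, 5 with median-ratio scaling, 7 with a filter of 100 RPM and 5 without His-GTG, and the number lower (0) was 2 in RPM, 6 with median-ratio scaling and 4 without His-GTG. From 1cell to 256cell the number lower (4) was 2 with median-ratio scaling and 2 with a filter of 100 RPM. From 256cell to sphere the number higher (2) was 1 with that filter. From sphere to shield the number higher (0) was 2 in RPM and 3 with median-ratio scaling, and the number lower (8) was 0 in RPM, 0 with median-ratio scaling and 4 with a filter of 100 RPM. From shield to 24hpf the number higher (2) was 1 with a filter of 100 RPM, and the number lower (12) was 6 with median-ratio scaling, 5 with the filter and 7 without His-GTG.

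As percent of the library total, His-GTG held 59.2, 34.6, 49.2, 45.0, 62.0 and 69.1 from egg to 24hpf, and mitochondrial tRNAs 13.4, 23.5, 24.2, 20.1, 10.0 and 3.92, since this denominator includes reads in neither table. In RPM, 22 mitochondrial tRNAs were at least 2-fold lower at 24hpf than in egg (2 by share) and 15 in later than in earlier stages (0 by share). For single sequences the number higher (240) was 128 with a pseudocount of 10 RPM, 368 without a filter and 54 with a filter of 100 RPM, and the number lower (809) was 1355 without a filter and 125 with a filter of 100 RPM. At 10 RPM or more, 1813 sequences were detected in egg, 1934 at 1cell, 1816 at 256cell, 1927 at sphere, 1989 at shield and 1415 at 24hpf.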

Other observations

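The tests on sequence families, on the number of mitochondrial tRNAs and on splits of the libraries were chosen only after the results were seen. Several other anticodons differed in their mix of sequence families between egg and 24hpf. In Glu-TTC the leading family was at 5930 RPM in egg and 17135 RPM at 24hpf, while families with T9C and C17T were at -1.85 and -2.49 relative to it, and its part of the anticodon went from 54.4% to 83.2%. Families with 1 substitution were also lower against the lead in Cys-GCA (203 to 23.9 RPM, against 181 to 220 RPM in the lead) and Pro-TGG (161 to 20.5 RPM, against 253 to 227 RPM). In Arg-ACG the opposite held, with the lead at 803 and 1197 RPM and a family with 1 substitution at 334 and 2184 RPM. The Arg-ACG lead held 48.0% of its anticodon in egg and 27.1% at 24hpf, but also 26.2% at 1cell and 48.2% at 256cell, so this shift is no larger than that between egg and 1cell. A Gly-GCC family with A38G, C46T and A49T was at 3.10 RPM in egg and 479 RPM at 24hpf. It adds A49T to the family with A38G and C46T, and A49T also occurs alone against the lead. Whether A49T is a misread base or a separate tRNA sequence was not tested. The base change A58G, numbered on the main read, marks the family that was lower in Gln-CTG. In Gln-TTG, whose main read starts 1 nt later, the same change is A57G. There families with T33C were the higher ones at 24hpf, and 1 of them also carries A57G.

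The 2 kinds of sequence under the label Val-TAC parted at 24hpf. The 10 sequences with TTTACAC, which holds the anticodon, went from 162 RPM in egg to 212 at sphere, 550 at shield and 3583 at 24hpf, 18.8 times their share in egg (log2 4.24). The 10 others were at 152 RPM in egg, 195 at sphere and 278 at shield, and then at 69.8 RPM at 24hpf (log2 -1.34 against egg). The sum over the label understates the difference of the first kind.

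The exchange of sequence families within an anticodon was weighed against errors of copying or sequencing. Errors of the leading sequence at a steady or lower rate leave no family higher against it. Yet 24 families with 2 to 5 substitutions were higher against the lead by at least 1 on the log2 scale, of which 14 were in Gly-GCC, 6 in Asn-GTT and the rest in 3 other anticodons. Where the lead itself was lower at 24hpf, as in Gly-GCC and Gln-TTG, a family with steady RPM also counts as higher. The 24 families are not independent, since families nested in one anticodon could be errors of one higher family and a lost base can be read as substitutions here. A lower error rate at 24hpf stays open for the families that were lower: among minor families with 1 substitution, 59.8% of 102 were lower in His-GTG (27 by at least 1, against 6 higher by as much) and 76.4% of 72 in Asp-GTC, Glu-TTC and Lys-CTT, and 10 of 20 abundant families were lower by at least 1 (median -2.17). For the higher families a candidate explanation is that different tRNA genes of one anticodon supply egg and 24hpf embryo, and gene assignments, modifications left after ALKB treatment and replicate libraries were not tested.

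The lower mitochondrial share at 24hpf was weighed against 2 simple accounts. It was not confined to a few abundant tRNAs, since 22 of the 22 were at least 2-fold lower in RPM at 24hpf than at 256cell, with log2 values from -4.14 to -1.28. In amount, however, trnV (109016 RPM at 256cell, 18573 at 24hpf) and trnL2 (61044 and 10975 RPM) made up most of the difference in the total. Dilution of the whole mitochondrial pool by one factor, as cytoplasmic tRNA grows, could also leave the members' ratios alone. The SD of their log2 differences was 1.13 times that between 1cell and 256cell (0.67 against 0.60), which is neither smaller nor far larger. Between egg and 1cell the SD was 0.85, above the 0.67. Dilution therefore stays open. A biological difference between stages and a difference in RNA recovery cannot be told apart with 1 library each.

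The dominance of His-GTG may come from which molecules gave reads in the listed size range. Nearly all listed reads were 60 to 67 nt long, too short to span a tRNA, and among reads of at least 70 nt His-GTG held at most 6.65% in any of the 6 libraries. That fits a product of this length that is far more frequent for His-GTG than for other tRNAs, for example from a stop in reverse transcription. Whether the stop lies at a modified base was not tested, and whether the table lists all long reads is not given in the sources used here.

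In the edgeR test of later against earlier stages, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many called anticodons as the real one, which was the real split itself with 1 call, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.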
